A study of Mus musculus with 32 samples.

How the data were processed

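Single-nucleus RNA was measured in the dorsal and the ventral hippocampus of male wild-type and 5xFAD mice at 8, 16 and 22 months of age. The 5xFAD line carries mutant human transgenes under the mouse Thy1 promoter. The labels list 32 libraries, 16 per region, which fall into 12 groups of genotype, region and age, with 3, 3 and 2 libraries per group at 8, 16 and 22 months. Each of 16 animals gave 1 dorsal and 1 ventral library, but the labels do not say which 2 libraries share an animal. Per the labels' protocols, nuclei were isolated from 4 to 11 mg of frozen tissue, 16500 nuclei were loaded per library on a Chromium 3' kit of version 3.1, and libraries were sequenced on NovaSeq6000 and NextSeq2000 instruments.

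The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, as 32 filtered matrices of 32285 genes. Per the submitters' processing notes, the authors aligned the reads to mm10 with Cell Ranger 7.1.0, whereas the matrices' own header lines name Cell Ranger 9.0.1. The authors' annotation of cells was not used here, and cell types were rebuilt from the counts. Gene symbols are those of the files, and 32235 gene identifiers matched the GENCODE M21 annotation of GRCm38 (mm10), from which all coordinates come.

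The files hold 259173 barcodes, from 2891 to 17083 per library. Total UMIs per library ran from 23637514 to 75281203, with a median of 45184936.5. Barcodes with at least 500 detected genes and at most 5% of UMIs from mitochondrial genes were kept, which left 245466. Doublets were called per library with Scrublet, through scanpy 1.11.5, at an expected rate of 8%. In 4 libraries its automatic threshold failed and the median threshold of the other libraries, 0.307, was used. It marked 10466 nuclei (4.26%), which were left out, so 235000 nuclei remained, from 2420 to 15277 per library. The median UMIs per nucleus ran from 1440 to 12890 between libraries, and the median detected genes from 980 to 4066. Intervals and floors of single genes below cover counting error only.

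Nuclei were clustered in Python 3.11.15 without the labels of genotype, region and age. The library entered as a batch when variable genes were picked. Up to 2500 nuclei per library (79920 in all) were scaled to 10000 UMIs and log-transformed. The 3000 most variable genes, 40 principal components and 20 neighbours entered Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.5 with seed 1. The other nuclei took the cluster of most of their 15 nearest neighbours (scikit-learn 1.9.0). A cluster was named for a cell class only from markers fixed before the data were examined, and every class name below means "like that class". Naming needed a mean marker score of at least 0.75, at least 3 detected markers, no larger number of another class's markers among its 10 leading genes, at most 15% called doublets and at most 50% of nuclei from 1 library. The limits on score, doublets and single libraries were set after seeing the clusters. Of 47 clusters, 24 were named, with 72.6% of the nuclei, and 67.1% lay in the 7 classes tested. Most unnamed nuclei were ventral, 24120 in 5xFAD and 25452 in wild type. In dorsal tissue 4979 nuclei of 5xFAD and 9834 of wild type were unnamed, so the unnamed part differed between regions and, in dorsal tissue, between genotypes.

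For each library and class, the raw UMI counts of all nuclei were summed, and these sums were tested across libraries. A library with fewer than 20 nuclei of a class left that class, which removed 1 ventral 5xFAD library from the CA3 class. The tests were edgeR 4.0.16 quasi-likelihood tests in R 4.3.3 (TMM normalization, filterByExpr, robust fit). Benjamini-Hochberg adjustment ran over all pairs of a class and a gene of a comparison together, with a threshold of 0.05. Every "adjusted p" of a gene below is from this edgeR test unless another tool is named. Genotype was tested in the 16 libraries of each region as the mean of the differences at the 3 ages. Age was tested as a slope within wild type, printed as the log2 change over 14 months, and age by genotype as the difference of the slopes. Region in wild type and genotype by region were tested in all 32 libraries with 12 group means. The share of each class among all nuclei of a library was compared by exact two-sided permutation of genotype within age (2400 assignments).

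Lists of genes were also fixed before the data were examined. They were disease-associated and homeostatic microglia, reactive and homeostatic astrocyte, disease-associated oligodendrocyte, myelin, cholesterol biosynthesis, interferon response, MHC class I presentation, heat shock and chaperone, immediate early, oxidative phosphorylation, synaptic, and dorsal and ventral hippocampus genes, with hemoglobin genes as a check for blood. Each was tested with limma 3.58.1's camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. The p-values were adjusted over the 82 tests of a kind of comparison in both regions, or 47 for comparisons across regions. Testing the cholesterol list in the 4 neuron classes was added after the genotype results were seen, as a family of 8 tests (4 across regions). The genes named were fixed by rule. For genotype, these are the 3 largest rises and 2 largest falls per class among genes past the threshold, with the same sign at all 3 ages and at least 20 CPM (UMI counts scaled to the class total, per 1e6) in the higher genotype. For region, they are the 2 largest changes per class in each direction. Named list members and any gene said to be chosen later come on top. Models without a proper name were skipped. Some genes that the rule or a list names are not reported here. Where 1 group holds no count, the fold is a lower bound against 3 counts over the group's nuclei.

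Free RNA was measured as the UMIs per 1000 nuclei of 9 microglial genes and of Thy1 in every class. A call was described as near background when the class held less than 2 times the UMIs per nucleus of the lowest other class, in the group where the gene was higher.

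Whether neighbouring library numbers may pair the 2 regions of an animal was examined on the residuals of the 12 groups. The correlation was over 0.1 in all 16 neighbouring pairs, from 0.116 to 0.779, and 15 of the 16 dorsal libraries correlated best with their neighbour. The highest correlation of any other pair was 0.561. At 22 months, where a group has 2 libraries, the residuals mirror each other. Both neighbouring pairs of a genotype then give the same value, 0.116 in 5xFAD and 0.521 in wild type, and do not count apart. Such correlations cannot tell a shared animal from anything else that neighbouring libraries share. The pairing is thus an assumption that the labels do not state. The fits across regions were repeated with these pairs as a block.

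The simulations changed only genes of at least 20 CPM, drew each gene independently and adjusted within the class. Recovery in the real tests can thus be lower. On simulated counts with 200 genes changed, the dorsal genotype test recovered 71.6% of 1.5-fold and 100% of 2-fold changes in the CA1 class. In microglia it recovered 11.9%, 50.7% and 93.9% at 1.5-, 2- and 4-fold. The dorsal age test in wild type recovered 4.5%, 62.7% and 100% of such changes in the CA1 class and 40.9% of 4-fold changes in microglia. The dorsal age by genotype test recovered 26.9% of 2-fold and 92.4% of 4-fold changes in the CA1 class and 24.2% of 4-fold changes in microglia. The genotype by region test recovered 80.6% of 2-fold changes in the CA1 class and 72.7% of 4-fold changes in microglia. Each gene test was also repeated on other random splits of the same libraries, with 24 splits per region and 21 across regions, the real split included. At an unadjusted p under 0.05, the share test called 93.8% of simulated differences of 2 SD and 4.4% of draws with no difference.

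The alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, a minimum of 1000 genes per nucleus, doublets kept, adjustment within each class, leaving out each library in turn, 22 against 8 month means in place of slopes, and other denominators for shares. With at least 1000 genes, microglia of wild type at 22 months held too few nuclei, so that class used the other ages for genotype and region. Alternatives added after seeing the data left out 9 libraries of over 13000 barcodes, or 5 libraries with few CA3 nuclei or over 45% of a cluster, or calls near background. Nuclei of unnamed clusters entered no gene test. Of the other named classes, Cajal-Retzius cells (871 nuclei) and fibroblasts (723 nuclei) entered no comparison, and the rest only the comparison of shares, apart from oligodendrocyte precursors.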

Results

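Nuclei from the dorsal and the ventral hippocampus of male wild-type and 5xFAD mice were profiled at 8, 16 and 22 months. Each combination of genotype and region had 8 libraries, with 3, 3 and 2 at the 3 ages. The 32 libraries held from 23637514 to 75281203 UMIs each. The comparisons ask how the transgenes change the cells of each end of the hippocampus, whether age changes them, and how far the 2 ends differ.

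The label check used Thy1, whose promoter drives the transgenes, summed over the excitatory neuron classes. In dorsal libraries Thy1 stood at 653.6 ± 264 CPM in 5xFAD against 115.4 ± 58.7 in wild type (mean ± SD, n = 8 each). In ventral libraries it stood at 1118 ± 593 against 85.5 ± 25.6 (n = 8 each). The lowest 5xFAD library lay above the highest wild-type one in both regions, at 390.2 against 195.6 CPM in dorsal and 528.2 against 134.4 CPM in ventral libraries. App did not separate the genotypes, at 558.7 ± 60.4 against 575.8 ± 115.9 CPM in dorsal libraries and 701.6 ± 108.2 against 560.0 ± 55.9 in ventral ones (n = 8 each). How much human sequence aligns to the mouse genes is not known.

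Among the nuclei recovered, the share of microglia was higher and that of astrocytes lower in 5xFAD mice in both regions. Microglia are the resident immune cells of the brain and gather around amyloid, and astrocytes are its main support cells. In dorsal tissue, microglia were 6.82 ± 1.51% of all nuclei in 5xFAD against 2.42 ± 0.825% in wild type (SD, n = 8 each, exact permutation p = 0.000833, adjusted p = 0.00667). In ventral tissue, they were 5.98 ± 0.906% against 1.72 ± 0.659% (n = 8 each, exact permutation p = 0.000833, adjusted p = 0.00667). Here 0.000833 is the smallest p the 2400 assignments can give, and all 8 of the 5xFAD libraries of each region lay above the wild-type mean. Astrocytes fell to 2.43 ± 0.922% from 5.15 ± 1.37% in dorsal tissue (n = 8 each, exact permutation p = 0.000833, adjusted p = 0.00667). In ventral tissue they fell to 4.56 ± 1.11% from 9.00 ± 2.19% (n = 8 each, exact permutation p = 0.0025, adjusted p = 0.015). None (0 of 8) of the 5xFAD libraries in either region reached the wild-type mean. With at least 1000 genes per nucleus, the astrocyte difference no longer passed in either region. It was then 2.18 ± 0.736% against 3.78 ± 2.19% in dorsal tissue (n = 8 each, unadjusted exact permutation p = 0.0958) and 3.63 ± 1.30% against 7.30 ± 2.99% in ventral tissue (n = 8 each, unadjusted exact permutation p = 0.0275).

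The other 20 shares of the 24 tested did not pass. The closest were dorsal endothelial and mural cells, at 0.663 ± 0.321% against 0.416 ± 0.133% (n = 8 each, exact permutation p = 0.0142, adjusted p = 0.068), and dorsal oligodendrocytes, at 9.77 ± 2.61% against 7.59 ± 1.48% (n = 8 each, exact permutation p = 0.0192, adjusted p = 0.0767). Oligodendrocyte precursors were at 2.40 ± 0.494% against 2.14 ± 0.344% in dorsal tissue, with an adjusted p of 0.43 by exact permutation (n = 8 each). Cluster 28 carried astrocyte markers but over 15% called doublets and stayed unnamed. Osmr, Aspg, Ggta1 and Gfap of the reactive astrocyte list were among its leading genes. This cluster was left out of the astrocyte share above and of the astrocyte gene tests below. It held 0.628% of dorsal nuclei in 5xFAD against 0.0887% in wild type (n = 8 each, exact permutation, adjusted p = 0.0192), and 0.250% against 0.0924% of ventral nuclei (n = 8 each, exact permutation, adjusted p = 0.307). Clusters 6, 32 and 36, also kept unnamed by limits set later, were nearest to CA1 and oligodendrocytes. Cluster 6 held 2.36% of ventral nuclei in 5xFAD against 1.30% in wild type, and clusters 32 and 36 held at most 0.260% in any group.

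**Figure D1:**
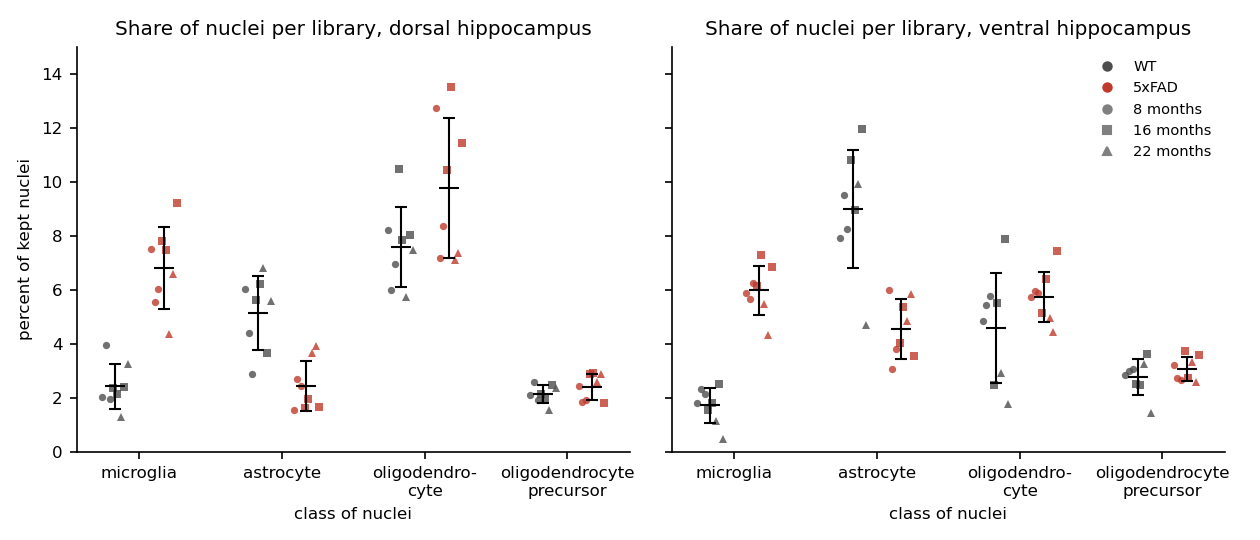
Share of 4 glial classes in each library, in percent of all nuclei kept, by region and genotype. Points are libraries, shaped by age, and black marks are means with SD (n = 8 per group); microglia averaged 6.82% against 2.42% in dorsal tissue and astrocytes 2.43% against 5.15%.

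Microglia of 5xFAD mice raised most genes of the disease-associated list, and some genes of the homeostatic list were lower. Over the 7 classes, edgeR called 672 pairs of a class and a gene in dorsal tissue (608 higher in 5xFAD) and 586 in ventral tissue (467 higher). Without 1 of the 22 month libraries the dorsal count fell to 329 (replicate 31), 358 (replicate 25) or 440 (replicate 23), and the ventral count to 369 (replicate 22). In dorsal microglia 320 genes passed (286 higher, 34 lower) and 320 in ventral microglia (235 higher, 85 lower). Pooled over libraries, the class was mostly cluster 38 in 5xFAD (62.7% of dorsal and 70.8% of ventral microglia) and cluster 15 in wild type (97.4% and 98.3%). Of the disease-associated microglia list, 20 of 23 measured genes rose in dorsal microglia and none fell. Adjusted over the list alone, 22 passed. The median log2 change was 2.23 (camera adjusted p = 5.78e-32, and adjusted p = 0.00302 with an estimated correlation). In ventral microglia 18 of 21 rose, and 20 adjusted over the list alone, with a median of 1.95 (camera adjusted p = 9.04e-35, and adjusted p = 2.29e-05 with an estimated correlation). Every measured member had a positive sign in both regions. Both medians were the same with Dkk2, Spp1 and Itgax, which had no wild-type count in a region, at their bounds. At 8, 16 and 22 months the dorsal medians were 2.55, 1.62 and 1.84, and the ventral ones 2.19, 1.52 and 2.13.

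Apoe, which codes for a lipid carrier, rose by 2.17 in dorsal microglia (SE 0.262, adjusted p = 0.000143), from 979.7 to 4500 CPM, and by 2.20 in ventral microglia (SE 0.216, adjusted p = 9.56e-07). The lipid receptor gene Trem2 rose by 1.07 (adjusted p = 0.0177) and 1.26 (adjusted p = 0.00011). Cst7, which codes for a cathepsin inhibitor (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), was at 148.0 ± 43.6 CPM against 1.79 ± 4.05 in dorsal microglia (n = 8 each, edgeR adjusted p = 1.67e-07). With 3 wild-type counts, its ratio was 72.0 (95% interval 24.5 to 350.0 from counting alone). Dkk2, a Wnt pathway antagonist gene (ENSMUSG00000028031, chromosome 3, 132085292 to 132180304), was at 194.8 ± 99.5 CPM in dorsal 5xFAD microglia, with no count in wild type, at least 97.3-fold higher. Mamdc2 (ENSMUSG00000033207, chromosome 19, 23302609 to 23448442) was at 210.3 ± 117.2 CPM against 0, at least 106.0-fold higher. In ventral microglia Ctse, a cathepsin gene (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), was at 153.0 ± 40.8 CPM against 0, at least 46.9-fold higher, and Dkk2 was at least 50.6-fold higher. Lilrb4a, an inhibitory receptor gene, had 1 wild-type count there and a ratio of 147.0 (95% interval 26.2 to 5810 from counting alone). These genes lay above every wild-type library in 8 of 8 5xFAD libraries.

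The named falls in microglia include Bank1, an adaptor gene known from B cells (ENSMUSG00000037922, chromosome 3, 136053363 to 136326066). Its log2 change was -1.89 in dorsal microglia (SE 0.210, adjusted p = 2.23e-05) and -2.36 in ventral microglia (SE 0.226, adjusted p = 3.59e-07), with 8 of 8 5xFAD libraries below all wild-type ones in both. The other named falls were Fcrl1 in dorsal microglia (-3.21, adjusted p = 0.0179), whose libraries overlapped between genotypes, and Ccdc162 in ventral microglia (-2.22, adjusted p = 0.0462). Of the homeostatic microglia list, 3 of 15 fell in dorsal microglia, namely P2ry12 (-0.78), Fcrls (-1.01) and Tmem119 (-0.91), and 7 adjusted over the list alone. In ventral microglia 5 of 14 fell, P2ry13 and Selplg besides the same genes, and 11 adjusted over the list alone. The list medians were -0.37 and -0.65 (camera adjusted p = 2.69e-05 and 1.61e-09). At 8, 16 and 22 months they were -0.02, -0.93 and -0.27 in dorsal and -0.40, -1.04 and -0.46 in ventral microglia. These 2 calls were lost when the correlation was estimated, with adjusted p = 0.362 and adjusted p = 0.138 with an estimated correlation. MHC class I genes B2m, H2-K1 and H2-D1 rose in microglia of both regions, 3 of 10 measured members in dorsal and 3 of 6 in ventral tissue (4 and 4 adjusted over the list alone). The list medians were 0.96 and 1.42 (camera adjusted p = 0.000377 and 0.00124, lost with adjusted p = 0.0669 and adjusted p = 0.147 with an estimated correlation).

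**Figure D2:**
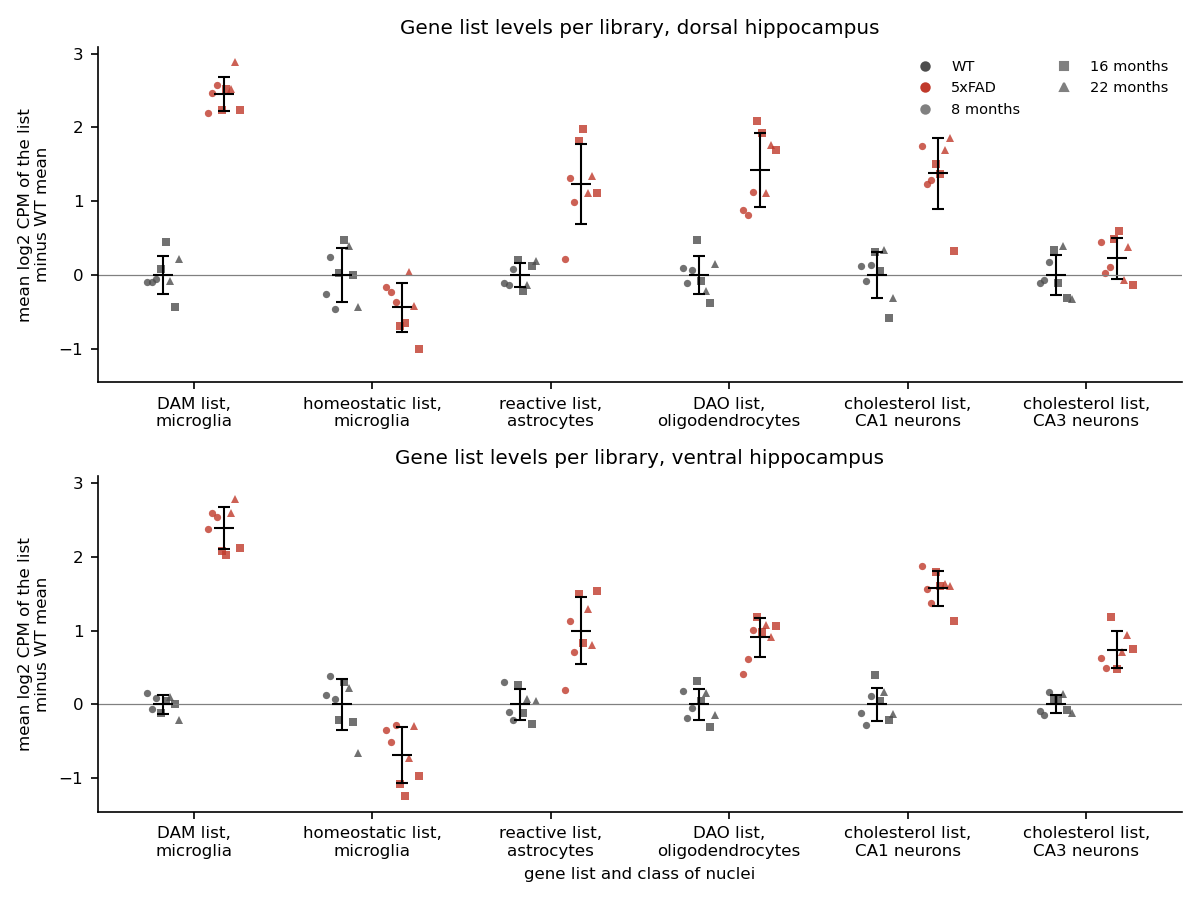
Mean log2 CPM of each gene list per library minus the wild-type mean of its region, in the class named under it. Points are libraries, shaped by age, and black marks are means with SD (n = 8 per group, 7 for ventral CA3 in 5xFAD); disease-associated microglia genes averaged 2.46 in dorsal and 2.39 in ventral 5xFAD microglia, and cholesterol biosynthesis genes 1.38 and 1.57 in CA1.

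Microglial transcripts were also found in the 6 other classes tested, at a like level. In dorsal 5xFAD tissue the 9 microglial genes gave from 565.7 to 611.1 UMIs per 1000 nuclei in the 6 other classes tested, against 6327 in microglia. In wild type they gave from 113.3 to 144.3 in those classes. In ventral 5xFAD tissue the range was from 456.9 to 502.8, against 5169 in microglia. Thy1 gave from 1729 to 1764 UMIs per 1000 nuclei in dorsal 5xFAD glia (astrocytes, oligodendrocytes and microglia), against 10240 in CA1. Of the 672 genotype calls in dorsal tissue, 140 were near this background, and 124 of 586 in ventral tissue. They include calls for Trem2, Tyrobp, Cst7, Lyz2 and C1qa outside microglia, and ventral calls for Thy1 outside CA1.

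**Figure D3:**
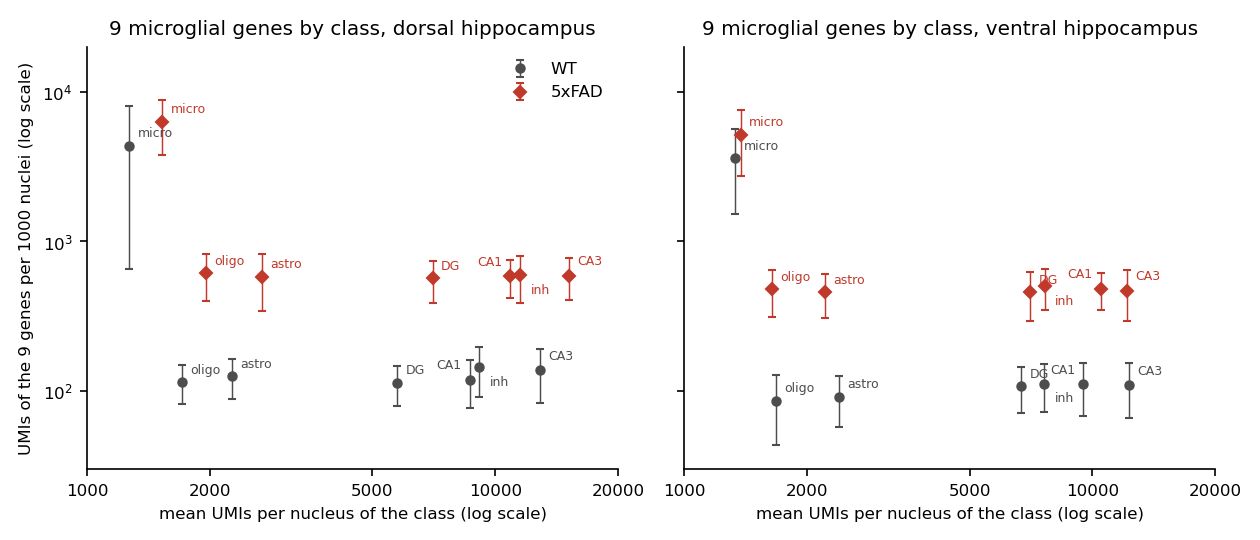
UMIs of 9 microglial genes per 1000 nuclei in each class, against the mean UMIs per nucleus of the class, both on log axes, by region and genotype. Points are means over libraries with SD (n = 8, or 7 for ventral CA3 in 5xFAD); in dorsal 5xFAD tissue the 6 classes other than microglia lie between 565.7 and 611.1.

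CA1 pyramidal neurons, the main output cells of the hippocampus, raised the genes of cholesterol synthesis in 5xFAD mice. Srebf2 codes for the transcription factor that drives this pathway and Sqle for an enzyme of it. By edgeR, 125 genes passed in dorsal CA1 (116 higher, 9 lower) and 131 in ventral CA1 (111 higher, 20 lower), and 55 of the higher ones passed in both regions. All 16 genes of the cholesterol biosynthesis list rose in CA1 in both regions, with or without adjustment over the list alone. Dorsal examples are Sqle (log2 change 1.77), Insig1 (1.72) and Srebf2 (0.74), and in ventral CA1 these were 1.84, 1.69 and 0.89. The list medians were 1.36 in dorsal (camera adjusted p = 5.68e-36, and adjusted p = 0.00789 with an estimated correlation) and 1.59 in ventral CA1 (camera adjusted p = 5.86e-54, and adjusted p = 0.000941 with an estimated correlation). Stard4, which codes for a sterol transport protein (ENSMUSG00000024378, chromosome 18, 33199355 to 33213862), rose by 2.47 in ventral CA1 (adjusted p = 7.47e-06), and by 2.26 in dorsal CA1. Testing this list in neurons was decided after these calls were seen. Per age, the list medians in dorsal CA1 were 1.47, 1.12 and 1.70 at 8, 16 and 22 months, and in ventral CA1 1.69, 1.56 and 1.53.

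The same list moved less in the other neurons. In ventral CA3, 7 of 16 genes rose, and 16 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.21e-31, and adjusted p = 0.000941 with an estimated correlation). Msmo1 rose there by 1.02 (SE 0.179, adjusted p = 0.012), above all wild-type libraries in 7 of 7. In dorsal CA3 0 of 16 passed, with a median of 0.21 (camera adjusted p = 8.05e-05, lost at adjusted p = 0.177 with an estimated correlation). The medians were 0.20 and 0.33 in dorsal and ventral inhibitory neurons and 0.16 and 0.17 in dorsal and ventral DG granule neurons, with 0 genes past the threshold (1 in ventral inhibitory neurons adjusted over the list alone). Of these only ventral inhibitory neurons passed when the correlation was estimated, at adjusted p = 0.0472 with an estimated correlation, and the other 3 gave adjusted p = 0.177 with an estimated correlation. In astrocytes 0 of 16 genes of the list passed in either region (camera adjusted p = 0.602 and 0.992), and 0 of 15 in dorsal oligodendrocytes (0.605). Ventral oligodendrocytes had 1 of 14 (Fdps, 3 adjusted over the list alone) and a median of 0.40 (camera adjusted p = 2.14e-05, lost at adjusted p = 0.138 with an estimated correlation). In ventral 5xFAD tissue the list's mean UMIs per 1000 nuclei were higher by 6733 in CA1 and 2383 in CA3. They were higher by 436.7 in inhibitory neurons, 395.5 in microglia, 287.6 in oligodendrocytes and 273.8 in granule neurons. In astrocytes the difference was -240.3. Whether free RNA accounts for the smaller rises was not tested.

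Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579) was the largest named rise in CA1, by 3.03 in dorsal (SE 0.290, adjusted p = 0.000132) and 3.95 in ventral CA1 (SE 0.254, adjusted p = 3.15e-06), in 8 of 8 libraries each. It rose by 2.41 in dorsal and 2.37 in ventral DG granule neurons, by 2.21 in ventral CA3 and by 2.01 in ventral inhibitory neurons. The ventral calls outside CA1 were near background. As the Thy1 promoter drives the transgenes, these values do not separate transgene transcripts from those of the mouse gene. Genes of ribosomal proteins, a set looked at after the calls were seen, rose in ventral CA1 for 23 of 77, with a median of 0.51. The unadjusted camera p with an estimated correlation was 0.0121, the smallest over all classes and regions. In dorsal CA1 8 of 77 rose, with a median of 0.42 (unadjusted camera p = 0.0586 with an estimated correlation). In the other dorsal neurons 0 of 77 passed, and the medians were -0.22 in granule neurons, -0.37 in CA3 and -0.37 in inhibitory neurons (unadjusted camera p = 0.424, 0.179 and 0.285 with an estimated correlation). In ventral tissue 0 of 77 passed too, with medians of -0.044 in granule neurons, -0.069 in CA3, -0.034 in inhibitory neurons and 0.132 in astrocytes. Falls in CA1 were smaller. The synaptic adhesion gene Lrrtm1 changed by -0.38 in dorsal CA1 (SE 0.0753, adjusted p = 0.0328). Serinc2, which codes for a serine incorporator, changed by -1.07 (SE 0.203, adjusted p = 0.0227) and Maml3, a Notch co-activator gene, by -0.74 (SE 0.102, adjusted p = 0.0016) in ventral CA1. Gfap rose by 1.87 in dorsal CA1 (adjusted p = 0.041), at 27.3 CPM, which is near background.

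**Figure D4:**
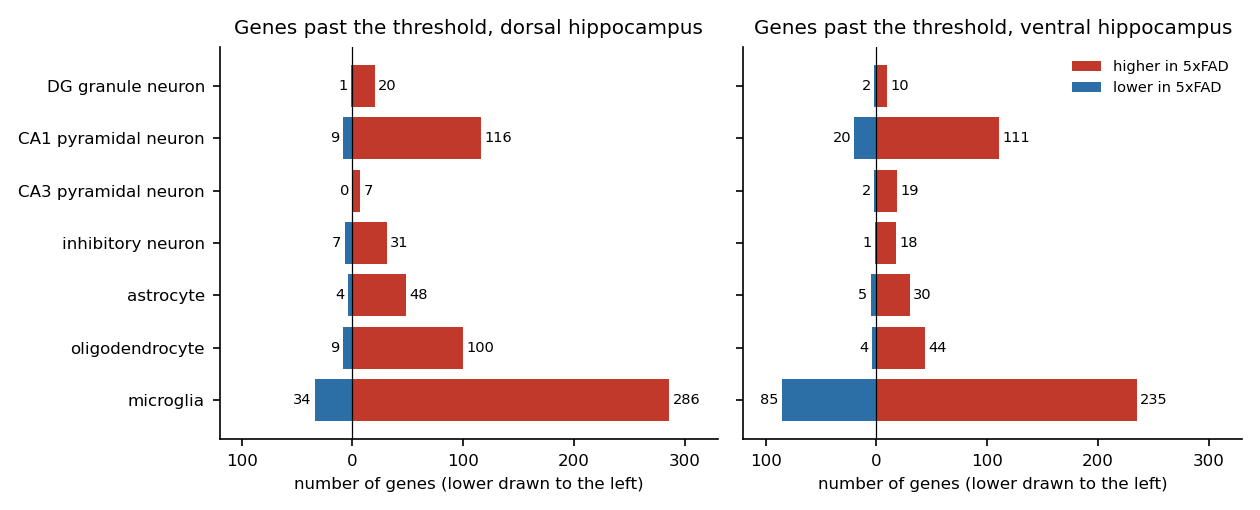
Number of genes past the threshold per class, higher and lower in 5xFAD, in dorsal and ventral tissue (edgeR, adjusted p under 0.05). Bars start at 0; microglia had 320 genes in each region and CA1 125 and 131.

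The other neuron classes had few genes past the threshold and the changes were small. Dorsal inhibitory neurons had 38 (31 higher, 7 lower) and ventral ones 19 (18 higher, 1 lower), of which 16 of the ventral ones were near background. In dorsal inhibitory neurons the genes were Ptchd1 (0.53, adjusted p = 0.0362), the growth hormone receptor gene Ghr (0.51, adjusted p = 0.012) and the cadherin gene Cdh18 (0.49, adjusted p = 0.0497). Mme (ENSMUSG00000027820, chromosome 3, 63241537 to 63386030) codes for neprilysin, an enzyme that degrades amyloid peptide. It fell by 0.79 in dorsal inhibitory neurons (SE 0.135, adjusted p = 0.00929), to 18.0 ± 3.73 from 31.6 ± 5.53 CPM (n = 8 each), in 8 of 8 libraries. Lgi2 changed by -0.65 there (adjusted p = 0.0239), and Rerg by 0.38 in ventral inhibitory neurons (adjusted p = 0.0411). Granule neurons of the dentate gyrus had 21 calls in dorsal and 12 in ventral tissue, 13 and 10 of them near background. Pooled over libraries, cluster 1 held 60.2% of dorsal granule neurons in 5xFAD against 33.8% in wild type and cluster 4 held 27.6% against 57.1%. These pooled shares were not tested across libraries, and 26.0% of cluster 4 came from 1 library. The axon guidance gene Slit2 rose by 0.57 in dorsal granule neurons (SE 0.105, adjusted p = 0.0207) and C1qa by 1.92 (adjusted p = 0.00937, near background). The sorting receptor gene Sorcs3 changed by -0.95 in ventral granule neurons (SE 0.182, adjusted p = 0.0263). CA3 had 7 calls in dorsal and 21 in ventral tissue, the latter from 15 libraries. They include Errfi1 (0.44, adjusted p = 0.0387) and Rnf182 (0.33, adjusted p = 0.0188) in dorsal CA3 and the Y-linked gene Eif2s3y in ventral CA3 (-0.40, adjusted p = 0.0484). Cluster 37 scored highest for CA3 markers but stayed unnamed, with an oligodendrocyte marker among its leading genes. Pooled over libraries, it held 1124 ventral nuclei in 5xFAD and 1509 in wild type. These lay outside the ventral CA3 class of 1948 and 3289 nuclei.

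Astrocytes of 5xFAD mice raised genes of the reactive state. By edgeR, 52 genes passed in dorsal astrocytes (48 higher, 4 lower) and 35 in ventral ones (30 higher, 5 lower). Of the reactive astrocyte list, 7 of 11 rose in dorsal astrocytes, and 10 adjusted over the list alone, with a median of 1.76 (camera adjusted p = 6.23e-22, and adjusted p = 0.00555 with an estimated correlation). In ventral astrocytes 4 of 12 rose, and 7 adjusted over the list alone, with a median of 1.21 (camera adjusted p = 6.16e-18, and adjusted p = 0.00645 with an estimated correlation). The intermediate filament gene Gfap rose by 2.01 in dorsal (SE 0.191, adjusted p = 4.98e-06) and 2.15 in ventral astrocytes (SE 0.308, adjusted p = 0.00399). The complement gene C4b rose by 1.76 and 1.58, and Cd44, a hyaluronan receptor gene, by 1.86 in dorsal astrocytes (adjusted p = 0.00678). Vim, another filament gene (ENSMUSG00000026728, chromosome 2, 13573927 to 13582826), rose by 2.45 in dorsal astrocytes (SE 0.351, adjusted p = 0.000732), in 7 of 8 libraries. Ventral Igfbp2, an insulin-like growth factor binding protein gene, changed by -0.99 (SE 0.199, adjusted p = 0.0174, 8 of 8 libraries below all wild-type ones) and Aff2 by -0.88 (adjusted p = 0.0236). Dorsal Spag7 (-1.38, adjusted p = 0.0324) and Actr3b (-0.74, adjusted p = 0.0332), and Trem2 and Tyrobp, which rose by 2.60 and 2.44 in dorsal and 3.05 and 3.33 in ventral astrocytes, were near background. No gene of the homeostatic astrocyte list passed in either region, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.165 and 0.889).

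Oligodendrocytes, the myelin-forming cells, raised the disease-associated oligodendrocyte and MHC class I lists in 5xFAD mice. By edgeR, 109 genes passed in dorsal oligodendrocytes (100 higher, 9 lower) and 48 in ventral ones (44 higher, 4 lower). Of the disease-associated oligodendrocyte list, 6 of 11 rose in dorsal tissue (9 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 4.05e-13, and adjusted p = 0.00555 with an estimated correlation). In ventral tissue 5 of 10 rose (7 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 6.52e-13, and adjusted p = 0.00555 with an estimated correlation). C4b rose by 1.65 and 1.71, Serpina3n by 1.94 and 1.57, and H2-D1 by 3.20 (SE 0.469, adjusted p = 0.00191) and 2.96 (SE 0.531, adjusted p = 0.00363). B2m rose too but was near background. The MHC class I list overlaps this one in B2m, H2-D1 and H2-K1. It rose for 4 of 5 in dorsal oligodendrocytes (4 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 2.26e-10, and adjusted p = 0.00555 with an estimated correlation). In ventral oligodendrocytes it rose for 3 of 4 (3 adjusted over the list alone), with a median of 1.60 (camera adjusted p = 6.41e-08, and adjusted p = 0.0106 with an estimated correlation). At 8, 16 and 22 months the MHC class I medians were 1.64, 4.30 and 1.99 in dorsal and 1.53, 2.14 and 1.14 in ventral oligodendrocytes. Dorsal oligodendrocytes also raised the mechanosensitive channel gene Piezo2 (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183) by 3.71 (SE 0.346, adjusted p = 9.56e-06), to 92.1 ± 56.1 from 8.08 ± 5.41 CPM (n = 8 each). Klk6, a protease gene, rose by 3.67 (SE 0.534, adjusted p = 0.00127) and Bcl3, which codes for a regulator of NF-kappaB, by 5.15 (SE 0.635, adjusted p = 0.00019), from 8 wild-type counts. Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) fell by 1.24 (SE 0.208, adjusted p = 0.00424), in 8 of 8 libraries, and Ccn3 changed by -1.44 (adjusted p = 0.00953, near background). In ventral oligodendrocytes the extracellular matrix gene Fbn2 changed by -0.92 (adjusted p = 0.0242) and Hdac9 by -0.87 (adjusted p = 0.0153, near background), while Trem2 (3.93) and Tyrobp (3.15) rose near background. No myelin gene passed (0 of 13 in each region, camera adjusted p = 0.452 and 0.872).

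The interferon response, heat shock and oxidative phosphorylation lists had few single genes past the threshold, and most of their list calls were lost with an estimated correlation. The interferon list rose in dorsal astrocytes with a median of 0.55, with 0 of 6 genes past the threshold and 1 adjusted over the list alone (camera adjusted p = 5.24e-05, and adjusted p = 0.0109 with an estimated correlation). It rose in ventral oligodendrocytes with a median of 0.45 and 1 of 5 genes past the threshold (camera adjusted p = 8.79e-06, lost at adjusted p = 0.0736 with an estimated correlation). In microglia its medians were 0.85 in dorsal (camera adjusted p = 0.0151, lost at adjusted p = 0.49 with an estimated correlation) and 0.75 in ventral tissue (camera adjusted p = 8.43e-05, lost at adjusted p = 0.18 with an estimated correlation), with 0 of 12 genes past the threshold in each and 0 and 7 adjusted over the list alone. Heat shock and chaperone genes were lower in the 4 dorsal neuron classes, with 0 genes past the threshold and medians from -0.48 in inhibitory neurons (camera adjusted p = 5.44e-07, lost at adjusted p = 0.258 with an estimated correlation) to -0.30 in granule neurons (8.2e-05, lost at adjusted p = 0.384 with an estimated correlation). Adjusted over the list alone, 9 of 16 passed in dorsal inhibitory neurons. Oxidative phosphorylation genes were lower in the same classes, with 0 of 22 genes past the threshold and medians from -0.43 in inhibitory neurons (camera adjusted p = 1.74e-07, lost at adjusted p = 0.384 with an estimated correlation) to -0.23 in CA1 (0.00904, lost at adjusted p = 0.654 with an estimated correlation). Immediate early genes, markers of recent activity, were lower in dorsal granule neurons (median -0.27, camera adjusted p = 0.000377, lost at adjusted p = 0.421 with an estimated correlation) and in dorsal inhibitory neurons (median -0.38, camera adjusted p = 0.00277, lost at adjusted p = 0.384 with an estimated correlation), where Nr4a2 passed. Synaptic genes had 0 of 24 past the threshold in all 4 neuron classes of both regions. Their list rose in ventral granule neurons by a median of 0.08 (camera adjusted p = 0.0037, lost at adjusted p = 0.1 with an estimated correlation). Outside glia, MHC class I genes had 1 call, H2-D1 in CA1 of both regions (camera adjusted p = 0.00979 and 0.0065, lost at adjusted p = 0.242 and 0.3 with an estimated correlation). In ventral astrocytes B2m was called (camera adjusted p = 1.92e-06, lost at adjusted p = 0.113 with an estimated correlation).

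Many of the genes that changed with genotype did so in both regions. Of 83723 pairs of a class and a gene tested in both regions, 565 were higher in 5xFAD in dorsal and 461 in ventral tissue, and 306 in both. Lists independent within each class would share 9.31, summed over the classes. Lower were 62 and 118, and 23 in both, against 0.382 on the same basis. Microglia held 186 of the 306 shared rises and 22 of the 23 shared falls. Oligodendrocytes held the other shared fall, and no fall passed in both regions in neurons or astrocytes. No pair passed in opposite directions, and 847 of the 877 pairs past the threshold in either region had the same sign in both. Both regions came from the same animals, so part of the overlap may come from differences between animals. The test of the difference itself, genotype by region, gave 0 pairs past the threshold by edgeR (smallest adjusted p = 1), with 4018 at an unadjusted p under 0.05 and 0 past the threshold by DESeq2. With neighbouring library numbers as a block, an assumed pairing, 23 pairs passed. Among them was Thy1, which rose more in ventral than in dorsal CA1 (0.89, adjusted p = 0.0178) and CA3 (1.13, adjusted p = 0.0113). In ventral CA3 the Thy1 genotype call was near background. Prkcb and Sncb, genes known from neurons, and Actr3b passed in astrocytes. These 5 pairs were named after their values were seen. Of the lists, cholesterol biosynthesis rose more in ventral than in dorsal CA3, by a median of 0.61 (camera adjusted p = 4.33e-12, and adjusted p = 0.0329 with an estimated correlation). In it 0 genes were past the threshold, and 3 adjusted over the list alone. This list test was added after the genotype results were seen and adjusted over 4 tests, against 47 for the planned list tests. Adjusted values of families this unlike cannot be compared, so its passing does not set it apart from the other lists. The other list calls of genotype by region were lost, at adjusted p = 0.316 or above with an estimated correlation, and the block moved the synaptic list of granule neurons past the threshold only at the preset correlation (camera adjusted p = 0.0222, lost at adjusted p = 0.634 with an estimated correlation).

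Age changed no single gene past the threshold in wild type. For a linear slope on months, taken over 14 months, edgeR gave 0 pairs in dorsal tissue (7833 at an unadjusted p under 0.05, smallest adjusted p = 0.166, 7 by DESeq2) and 0 in ventral tissue (7705, smallest adjusted p = 0.131, 51 by DESeq2). The genotype difference did not change with age past the threshold either, with 0 pairs in dorsal (3216 at an unadjusted p under 0.05, smallest adjusted p = 0.872, 0 by DESeq2) and 0 in ventral tissue (3449, smallest adjusted p = 0.966, 0 by DESeq2). In simulated data for dorsal tissue, 40.9% of 4-fold changes with age in wild-type microglia were recovered, and all (66 of 66) of those in CA1. These simulated changes were in genes of at least 20 CPM with adjustment within the class, so the real tests can recover fewer. As lists, heat shock genes moved up with age in 5xFAD relative to wild type in all 7 dorsal classes, with medians from 0.46 in oligodendrocytes (camera adjusted p = 0.00611) to 0.93 in CA3 (0.00099, both lost at adjusted p = 0.706 with an estimated correlation), and in ventral granule neurons, CA3, oligodendrocytes and microglia (medians from 0.32 to 0.62, lost at adjusted p = 0.675 or above with an estimated correlation). So did oxidative phosphorylation genes in all 4 neuron classes of both regions (medians from 0.39 to 0.62 in dorsal and from 0.21 to 0.51 in ventral tissue, lost at adjusted p = 0.706 or above with an estimated correlation). The interferon list moved down in ventral microglia (median -1.50, camera adjusted p = 2.34e-05, lost at adjusted p = 0.675 with an estimated correlation). All list calls of age by genotype were lost when the correlation was estimated, at adjusted p = 0.675 or above with an estimated correlation, and those of age in wild type at adjusted p = 0.953 with an estimated correlation.

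In neurons, more genes passed between the ends of the hippocampus than between the genotypes, from fits of 32 and 16 libraries. In wild type, edgeR gave 10415 of 93827 pairs past the threshold between ventral and dorsal tissue, 5490 higher in ventral and 4925 higher in dorsal tissue. CA1 had 4240, CA3 2251, granule neurons 2061, inhibitory neurons 1029, astrocytes 450, oligodendrocytes 240 and microglia 144. With neighbouring library numbers as a block, 18848 pairs passed. Different clusters held these neurons at the 2 ends, in nuclei pooled over libraries. Cluster 44 held 96.9% of ventral and clusters 11 and 12 46.9% and 52.0% of dorsal CA1 in wild type, and clusters 20 and 9 92.3% of ventral and 96.9% of dorsal CA3. All 7 genes of the ventral hippocampus list, such as Nr2f2, Grp and Trhr, were higher in ventral granule neurons, CA1 and CA3, with or without adjustment over the list alone. The medians were 2.78, 2.97 and 3.90 (camera adjusted p = 5.79e-12, 2.85e-08 and 3.16e-13). With an estimated correlation the list held in granule neurons and CA3 (adjusted p = 0.0204 each) and was lost in CA1 (adjusted p = 0.0741 with an estimated correlation). With the block and an estimated correlation, it was lost in granule neurons and CA3 as well (adjusted p = 0.0817 each). Of the 5 genes of the dorsal hippocampus list, Lct, Gsg1l and Stra6 were higher in dorsal granule neurons (median -0.71, camera adjusted p = 0.00438, lost at adjusted p = 0.0741 with an estimated correlation). Lct, Wfs1 and Gsg1l were higher in dorsal CA1, where Stra6 was higher in ventral nuclei (median -1.77, camera adjusted p = 0.0258, lost at adjusted p = 0.0758 with an estimated correlation, and at 0.0699 with the block). Lct alone was higher in dorsal CA3 (camera adjusted p = 0.436). Adjusted over the list alone the counts toward dorsal were 3, 3 and 1.

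The Notch ligand relative Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336) was higher in ventral than in dorsal tissue by 7.33 in CA1 (SE 0.807, adjusted p = 7.27e-07), at 11.1 ± 9.70 against 0.163 ± 0.253 CPM (n = 8 each), and by 6.16 in granule neurons. The collagen gene Col6a1 was higher by 6.97 in CA3 (SE 0.923, adjusted p = 1.34e-05). The cofactor gene Vgll3 was at 45.6 CPM in ventral CA3, above all dorsal libraries in 5 of 8, with 1 count in dorsal CA3 and a ratio of 1740 (95% interval 312.0 to 68900 from counting alone). Gpr139, an orphan receptor gene, had 2 dorsal counts in CA1 and a ratio of 108.0 (29.3 to 903.0). Toward dorsal tissue, the log2 change was -4.88 for the adhesion gene Clmp in granule neurons (SE 0.362, adjusted p = 2.28e-09), at 132.4 ± 34.0 against 5.30 ± 4.83 CPM (n = 8 each). It was -5.43 for the protein kinase C gene Prkcd in CA3 (SE 0.261, adjusted p = 2.44e-12), at 71.9 ± 22.5 against 1.88 ± 1.08 CPM (n = 8 each). Cd38 in CA3 (-6.37), Lrmp (-5.87) and Plekhg1 (-5.51) in CA1, Ighm in granule (-5.53) and inhibitory neurons (-4.80) and Nr1h4 in inhibitory neurons (-3.23) went the same way.

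Glia differed by region in fewer genes, of which many were near background (165 of 240 in oligodendrocytes and 132 of 144 in microglia). The nuclear receptor gene Nr2f2 was higher in ventral astrocytes by 3.29 (SE 0.325, adjusted p = 2.37e-08), at 70.7 ± 27.4 against 7.97 ± 5.87 CPM (n = 8 each). The transcription factor gene Trp63 (-3.39, adjusted p = 2.96e-07) and Ky (-3.55, adjusted p = 1.22e-05) were higher in dorsal astrocytes. Dcn, which codes for decorin, was higher in ventral granule neurons (5.29), inhibitory neurons (6.21), astrocytes (5.37), oligodendrocytes (6.83) and microglia (4.83), all near background, and so were Dlk1 in granule neurons, inhibitory neurons and oligodendrocytes. Lingo3 (-3.04) and Taf13 (-2.68) in oligodendrocytes and Nr2f2 (4.19), Zfhx4 (-3.44) and Ppp1r14a (higher in dorsal tissue, with 2 ventral counts) in microglia were near background too. Immediate early genes were higher in dorsal neurons, 6 of 17 in granule neurons, 8 of 18 in CA1 and 7 of 15 in CA3 (9, 9 and 7 adjusted over the list alone), among them Arc, Egr1 and Nr4a1, while Jun and Fosl2 were higher in ventral CA1 and CA3. The camera calls (adjusted p = 0.000171, 0.0258 and 0.0258) were lost at adjusted p = 0.457, 0.78 and 0.615 with an estimated correlation, and the block gave 0.053 in CA3. Synaptic genes were lower in ventral CA3 for 7 of 24 (14 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.65e-05, and adjusted p = 0.047 with an estimated correlation, lost at 0.333 with the block). Mal and Cnp of the 13 myelin genes were higher in dorsal oligodendrocytes (camera adjusted p = 0.0183, lost at adjusted p = 0.821 with an estimated correlation), and Kcnj10 and Slc1a2 of the homeostatic astrocyte list in dorsal astrocytes (camera adjusted p = 0.212). Ifit2 and Ifit3 of the interferon list were higher in dorsal inhibitory neurons (camera adjusted p = 0.0493, lost at adjusted p = 0.569 with an estimated correlation, and at 0.0597 with the block). The block also took oxidative phosphorylation (0.0284) and cholesterol biosynthesis genes (0.0164) in CA1 past the threshold, both lost with an estimated correlation (adjusted p = 0.764 and 0.558).

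Hemoglobin transcripts made up from 0.000198 to 0.0015% of the UMIs of a library.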

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

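The tests of the 3 patterns below, and the counts of other splits for dorsal tissue and for genotype in ventral tissue, were chosen or worded after the results were seen. The remaining splits were planned before.

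Genes of cholesterol synthesis rose in CA1 of 5xFAD mice in both regions, all 16 of the list. Another mix of CA1 clusters is argued against, because within each CA1 cluster the list's median log2 change was 1.339 or more. Free RNA from other cells is argued against too, because in granule neurons and glia the UMIs of the list rose by at most 10.03% of the rise in CA1. Without the libraries that held many barcodes or stood apart, the lowest median was 1.223. A response of CA1 neurons to the transgenes or to amyloid may account for it, as a hypothesis that no test here addresses, and the design cannot separate these causes.

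Microglial genes such as Trem2, Tyrobp and Lyz2 were called in neurons, astrocytes and oligodendrocytes of 5xFAD mice. Doublets with microglia are argued against, because nuclei with 4 or more of these UMIs held at most 14.44% of them in the other classes measured, against 84.61% in dorsal microglia. Free RNA in the droplets may be the source, because the highest mean of these UMIs per nucleus among the 6 other classes tested was 1.1 times the lowest in ventral tissue and 1.08 times in dorsal tissue, while mean UMIs of all genes per nucleus differed 7.42 and 7.74 times between these classes. Oligodendrocyte precursors lay above these classes, at 711.5 UMIs per 1000 nuclei in dorsal and 604.5 in ventral tissue. Whether any of these cells also make such transcripts at a low level stays open.

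The share of astrocyte-like nuclei was lower in 5xFAD mice in both regions, a change of -52.77% in dorsal and -49.31% in ventral tissue. Dilution by microglia is argued against, with a larger exact permutation p of 0.004167 among nuclei other than microglia. Astrocytes left in cluster 28 are argued against as the whole cause, with a larger exact permutation p of 0.0025 when it was counted as astrocytes. The change was then -41.57% in dorsal and -47.08% in ventral tissue, so this cluster may hold part of the dorsal fall. Loss of nuclei at the gene minimum cannot be told apart from a real fall, because with at least 1000 genes the dorsal change was -42.39% with a permutation p of 0.09583, and -25.76% with a p of 0.24 with cluster 28 added, while the ventral change stayed at -50.28% with a p of 0.0275. A lower number or yield of astrocyte nuclei may remain, and the design does not separate these.

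Other splits of the same libraries show how rarely a random split reached the real counts, but 24 or 21 splits are too few to exclude chance. For genotype in dorsal tissue the real split gave 672 pairs and the highest of the other splits 0, and in ventral tissue 586 against 36, so only 1 of 24 splits, the real one, reached that count in each. For region in wild type the real split gave 10415 pairs and the highest other 334, again 1 of 21 splits. For age and age by genotype the real count was 0, which all 24 splits reach by construction, so these splits say nothing about chance. The highest others were 0 for both in dorsal tissue, and 27 for age and 3 for age by genotype in ventral tissue. The same holds for genotype by region, where the real count and the highest other were 0 and all 21 splits reach it.

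A difference between groups marked 1 list, as cholesterol biosynthesis genes in CA3 differed between regions in their genotype effect (camera adjusted p = 0.0329 with an estimated correlation). That value was adjusted over 4 tests added after the genotype results were seen, against 47 for the planned list tests, so they cannot be compared. Oligodendrocyte precursors, a class outside the main gene tests, had 11 genes past the threshold for genotype in dorsal and 19 in ventral tissue by edgeR. Cluster 23, unnamed and in no gene test, held 0.2341% of dorsal nuclei in 5xFAD against 0.9951% in wild type, with an adjusted p of 0.01917 by exact permutation over 46 tests (n = 8 each), while its larger ventral share did not differ, at 3.534% against 3.806% (exact permutation, adjusted p = 0.8541). Of these tests, cluster 28 in dorsal tissue, given above, and cluster 39 in ventral tissue, at 0.252% in 5xFAD against 0.09139% in wild type, passed as well (exact permutation, adjusted p = 0.01917 and 0.02556). Cluster 39 had 39.24% called doublets and microglial genes among its leading ones, and its dorsal share was 0.06084% against 0.09087%.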

How the results depend on the processing

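Leaving out the libraries of over 13000 barcodes, or replicates 4, 14, 20, 23 and 32, or calls near background, was chosen after seeing the data. No named gene reversed its direction under any alternative, and of their values 2241 stayed past the threshold and 269 no longer passed. Counts of pairs for genotype moved in dorsal tissue from 672 to 1093 with DESeq2, 1283 with no filter on low counts, 385 with at least 1000 genes per nucleus and 440 without replicates 4, 14, 20, 23 and 32, of which only 23 is dorsal. In ventral tissue they moved from 586 to 948 with no filter and 369 without those replicates. Age in wild type moved from 0 in dorsal tissue to 7 with DESeq2, 185 with no filter, 1 for 22 against 8 months and 1 with adjustment within each class. In ventral tissue it moved from 0 to 51 with DESeq2, 14 with no filter, 1 within each class and 2 without the libraries of over 13000 barcodes. Age by genotype in dorsal tissue moved from 0 to 32 with no filter. Genotype by region moved from 0 to 3 with no filter, 1 without the libraries of over 13000 barcodes and 23 with the replicate block, and region in wild type from 10415 to 18848 with that block. The block changed no call of a gene named for region in wild type, and no list call besides those given above. Shares past the threshold moved from 4 to 2 with at least 1000 genes, where both astrocyte calls were lost, and list tests from 118 to 12 with an estimated correlation. Without the libraries of over 13000 barcodes, the cholesterol list in ventral inhibitory neurons had a median of 0.195 in place of 0.331, the only genotype list past the threshold with an estimated correlation to move over 1.5 times. Medians of lists lost with that correlation moved as well, such as homeostatic genes in dorsal microglia from -0.371 to -0.609 and oxidative phosphorylation in dorsal granule neurons from -0.343 to -0.185, or immediate early genes there from -0.266 to -0.154 without the 5 replicates. No called genotype list changed its sign. The cause was not tested for any of these. Leaving out 1 library at a time gave 329 to 731 pairs for genotype in dorsal and 369 to 713 in ventral tissue, 0 to 1 for age in ventral wild type, 0 to 1 for genotype by region, 7897 to 11054 for region and 3 to 5 shares. The dorsal count moved without replicate 31 (329), 25 (358) or 23 (440) and the ventral one without 22 (369), all from 22 months, where a group has 2 libraries and the last one is assumed to vary like the others. Age in ventral wild type gave 1 without replicate 22 or 30, and genotype by region 1 without 16. Simulations covered CA1 and microglia only, with adjustment within the class. Of 1.5-fold genotype changes in dorsal tissue 71.6% were recovered in CA1 and 11.9% in microglia.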

Other observations

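The look at oligodendrocyte precursors, the dividing cells that give rise to oligodendrocytes, was chosen after the other results were seen. By edgeR, 11 genes were higher in dorsal precursors of 5xFAD mice and none (0) lower, and 17 were higher and 2 lower in ventral precursors. The rule for calls near background was not applied to precursors, so none of these calls was checked against free RNA by it. Ermard rose by 2.57 in dorsal (adjusted p = 0.000211) and 2.28 in ventral precursors (adjusted p = 1.45e-10). The complement gene C4b rose by 2.42 and 3.64, as it did in oligodendrocytes of both regions. Piezo2 rose by 2.81 and 1.55, as it did in dorsal oligodendrocytes. The long noncoding gene Pvt1 rose by 0.97 and 0.86, Bcas1, a gene of newly forming oligodendrocytes, by 0.82 in dorsal precursors and Ddx60, an antiviral helicase gene, by 2.23 in ventral ones. The gap junction gene Gja1 (-1.32) and the transporter gene Slco1c1 (-2.64), known from astrocytes, were lower in ventral precursors, while Gfap, also known from astrocytes, was higher there (2.57, adjusted p = 0.0211). The share of astrocytes in ventral tissue was 4.56% in 5xFAD against 9.00% in wild type, and free RNA from astrocytes was not measured in precursors. Thy1, Trem2, Tyrobp and C1qa passed there as well. The 9 microglial genes gave 711.5 UMIs per 1000 nuclei in dorsal and 604.5 in ventral 5xFAD precursors, against 565.7 to 611.1 and 456.9 to 502.8 in the 6 other classes.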
